A study of Homo sapiens with 4 samples.

How the data were processed

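The series measured N6-methyladenosine (m6A) in the RNA of OMM2.3 cells, a human uveal melanoma cell line, by methylated RNA immunoprecipitation and sequencing (meRIP-seq). Poly(A) RNA was fragmented, part of it was sequenced as input, and fragments bound by beads carrying an antibody to m6A were sequenced as the immunoprecipitate (RIP), per the labels' protocols. Cells were exposed for 24 h to meclofenamic acid (MA) or to DMSO as the control (NC). There were 4 libraries, 1 input and 1 RIP library for each of MA and NC. No group had a replicate, so no p-value was computed and no SD or standard error across samples, and every difference below describes these libraries.

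The gene table holds FPKM values that the authors computed from the input libraries, 1 column for MA and 1 for NC. The submitters' processing notes name Trimmomatic, HISAT2, HISAT, deepTools and ChIPseeker and the build GRCh38.p13, without versions. The role of each aligner, the read counter, the gene annotation release and the filter behind the gene table are not given in the sources used here. The peak lists, 1 for MA and 1 for NC, give for each peak its position, exonic length, annotated feature and gene, per the file headers. The p-value and false discovery rate of each peak are the authors' own, per the file headers. The fold enrichment of RIP over input is likewise the authors' deposited value, and it was used only to describe, rank or filter peaks within its own list. The peak caller and its thresholds are not given in the sources used here. Every listed peak had a fold enrichment of at least 1.5. Rows that repeated the same peak were counted as 1 peak, which took 132 rows from the NC list and 99 from the MA list. Peak starts were raised by 1 so that positions count from 1.

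The depth of the input libraries was recovered from the FPKM values. The ratio of both values of a gene is a ratio of 2 whole read numbers times a constant, which gave the relative depth, and the value of 1 read then gave the product of gene length and library total. Of several candidate totals, the one kept gave lengths equal to the RefSeq span (GRCh38.p14 table, used for names and lengths only) in 145 genes, against 29 at the next best. The totals behind the per-million scale were 37041597 reads or fragments in NC and 41630895 in MA. Of 13055 genes above 0 in both inputs, 99.9% resolved to whole reads, and 0% did so once the values were moved by a small amount. Recovered reads are the smallest numbers that fit. In simulated libraries, 3000 genes were sampled, and those with reads in both libraries and resolved were checked. Of these, 84.0% had their true reads and length and the others a whole fraction of them. Intervals of a ratio are exact 95% binomial intervals from these minimum reads, which widens them where the minimum is below the true reads. They cover counting error only, and they are too narrow in so far as PCR reads without molecular identifiers are not independent molecules. Each exact Clopper-Pearson interval of a share of peaks or genes also covers counting error only.

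The main choices were fixed before the data were examined. Input differences are log2((MA FPKM + 1)/(NC FPKM + 1)) for genes at 1 FPKM or more in at least 1 input, which understates the difference of low genes. Genes at or beyond 2-fold were counted. For 34 fixed gene lists, the median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these libraries. A list stood apart when the percentile was at most 2.5, or as close to 100 at the other end. For genes with a peak in both lists, 1000 random lists were drawn. Peaks that touched or overlapped within a list on the same strand were merged to regions, and a region was shared when it overlapped a region of the other list on the same strand by at least 1 bp. Overlap was taken over the whole span from start to end, introns included. Of the list symbols, 1 was matched through its older symbol, and it was then counted a single time. In simulated libraries of 10564 genes with Poisson reads, 97.0% of 200 genes given a 4-fold difference were counted as 2-fold or more, against 0.00965% of the other genes. These libraries held counting error only, without variation between cultures or preparations, so the shares are not error rates of the real comparison. A simulated list of 20 genes 4-fold higher reached percentile 100, and 4% of 200 random lists of 15 genes stood apart.

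Named input genes are the 10 with the highest and the 10 with the lowest difference among genes at 5 FPKM or more in at least 1 input, outside chromosome Y. Within each fixed list, the 3 members with the largest absolute differences may be named, together with every m6A writer, eraser and reader. Named peaks are the 5 with the highest fold enrichment in each of 3 sets (shared, NC only and MA only) in genes at 5 FPKM or more in both inputs. Members of the fixed lists with a peak in a single list complete the rule. Alternatives covered the pseudocount, the filter on low values, rescaling, the overlap that counts as shared and a stricter peak threshold of fold 3 and false discovery rate 0.01. The planned comparison of RIP with input per gene and the planned motif share of peaks were not analysed here, and neither were mitochondrially encoded transcripts in the inputs. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.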

Results

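OMM2.3 uveal melanoma cells were compared after 24 h with meclofenamic acid (MA) or with DMSO as the control (NC). Meclofenamic acid is a nonsteroidal anti-inflammatory drug that blocks cyclooxygenases and also inhibits the m6A demethylase FTO, so the design asks how the m6A peaks and the transcript levels of these cells differ with the drug. Each condition had 1 input library, giving transcript levels, and 1 m6A RIP library, giving a list of peaks. The input totals recovered from the FPKM values were 37041597 for NC and 41630895 for MA. The gene table listed 14416 genes, and 10564 of them reached 1 FPKM in at least 1 input.

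In the inputs, ARRDC3, ID1, CCN1 and genes of sterol synthesis were highest with MA relative to NC, and melanocyte lineage genes were the lowest of the fixed gene lists. ARRDC3, a gene of the alpha-arrestin family, was at 41.5 FPKM in MA and 0.558 in NC, a log2 difference of 4.77. CCN1, a YAP target, was at 498 against 34.1 FPKM (log2 difference 3.83). The sterol genes HMGCS1 (141 against 9.51 FPKM, 3.76), MSMO1 (168 against 12.2, 3.68) and INSIG1 (98.4 against 11.5, 2.99) were also among the 10 highest. At the other end, SLC5A4, of the sodium-glucose transporter family, was at 0.842 FPKM in MA and 31.9 in NC (log2 difference -4.16).

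The rest of the 10 highest were ID1 (33.1 against 1.18 FPKM, log2 difference 3.97), SPX (66.2 against 4.87, 3.52), KLF4 (18.8 against 0.898, 3.38), KLF2 (39.6 against 3.44, 3.19) and ZNF441 (11.4 against 0.461, 3.08). ID1, KLF2 and KLF4 encode transcription regulators, and SPX encodes the peptide hormone spexin. After SLC5A4, the lowest were PRDM7 (4.79 FPKM in MA against 44.3 in NC, -2.97), HOXD1 (4.25 against 37.1, -2.86) and NANOS1 (4.13 against 35.8, -2.85). LOC107987373 (1.84 against 17.5, -2.71), MBP (8.40 against 56.1, -2.60) and GYG2 (4.10 against 29.1, -2.56) followed. The last of the 10 were TSPAN10 (0.993 against 10.8, -2.56), ST6GALNAC1 (0.644 against 8.51, -2.53) and SPATS1 (2.56 against 19.3, -2.51). PRDM7 has a near-identical paralog, PRDM9, so its reads are uncertain. Counting error was small beside these differences. Without a pseudocount the log2 ratio of ARRDC3 was 6.22 (95% interval 5.94 to 6.52), that of CCN1 3.87 (3.81 to 3.92) and that of SLC5A4 -5.24 (-5.56 to -4.94).

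**Figure D1:**
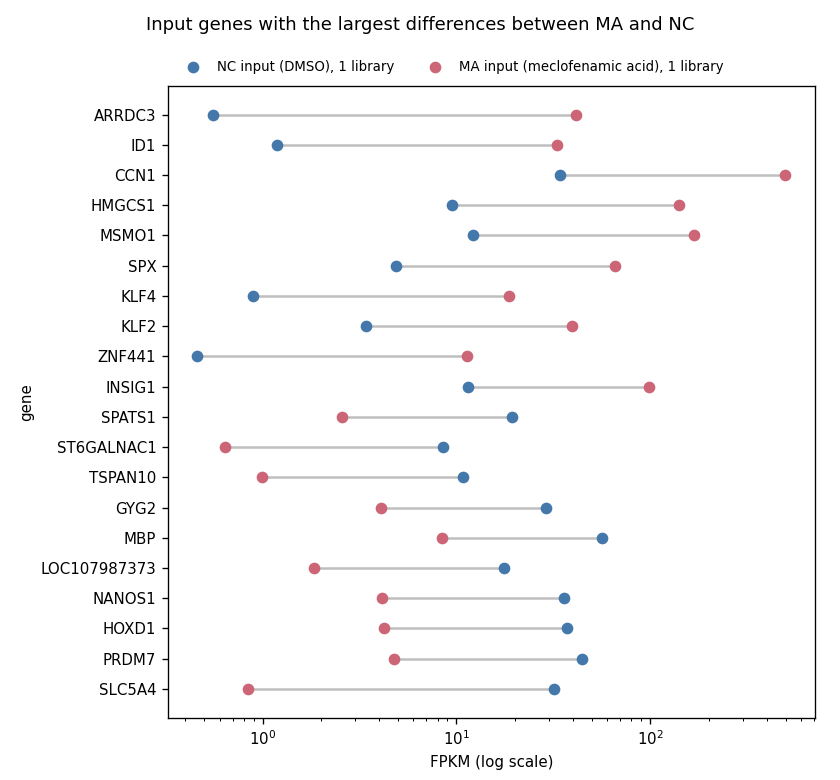
FPKM (log axis) of the 10 genes with the highest and the 10 with the lowest log2 difference in the MA input (red points) and the NC input (blue points), 1 library each, joined by a grey line. ARRDC3, at the top, was at 0.558 FPKM in NC and 41.5 in MA, and SLC5A4, at the bottom, was at 31.9 in NC and 0.842 in MA.

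Over all tested genes, 1087 were higher by 2-fold or more with MA, 315 were lower by 2-fold or more and 9162 lay between. The median gene had a log2 difference of 0.11, with the 10th percentile at -0.60 and the 90th at 1.01. After rescaling to a median difference of 0 the counts were 830 and 395, and with a pseudocount of 5 they were 273 and 154. The imbalance grew with transcript length: 233 genes were higher and 131 lower among the shortest of 3 equal groups by recovered length, against 457 and 79 among the longest.

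Of the 34 fixed lists, 29 had 3 or more tested genes. Of these, 14 stood apart from matched random lists, 12 above and 2 below, against 1.45 for lists of genes drawn at random. Members of a list can vary together and some lists share genes, such as SLC7A11, which the 1.45 does not take into account. Cholesterol synthesis genes were highest, with a median log2 difference of 1.49 over 16 genes, above all 10000 random lists. In this list 10 genes were higher by 2-fold or more and none was lower by as much, and the members went from -0.40 to 3.76. Genes of the G2 and M phases had a median of 0.67 over 21 genes, again above all 10000 random lists, with 9 higher by 2-fold. These included the kinesins CENPE (12.6 FPKM in MA against 3.18 in NC, 1.71) and KIF11 (15.9 against 5.21, 1.44) and the topoisomerase TOP2A (96.8 against 31.7, 1.58). In contrast, S phase genes had a median of -0.07 (percentile 63.3) and none of 20 reached 2-fold in either direction. FEN1 was at 45.1 against 76.8 FPKM (-0.76), RRM1 at 58.6 against 35.7 (0.70) and CCNE2 at 3.71 against 1.98 (0.66).

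Several stress response lists lay above random lists too. The NRF2 list, genes of the oxidative stress response, had a median of 0.65 over 14 genes (percentile 100), with SLC7A11, the cystine transporter subunit, at 35.7 FPKM in MA and 8.11 in NC (2.01). GCLM, of glutathione synthesis, was at 9.96 against 2.97 (1.47) and SRXN1 at 133 against 49.0 (1.43). p53 targets had a median of 0.49 over 19 genes (percentile 99.7), and 5 were higher by 2-fold, among them MDM2 (73.8 against 15.7 FPKM, 2.17), GADD45A (210 against 47.5, 2.12) and PMAIP1 (16.3 against 3.28, 2.02). Of the 19 p53 targets, 14 were above 0, and the members went from -0.27 to 2.17. CDKN1A, named after its values were seen, was at 6.49 against 7.38 (-0.16). The ATF4 list had a median of 0.20 over 18 genes (percentile 99.3), in which DDIT3 (435 against 75.1, 2.52) and ATF3 (74.8 against 18.5, 1.96) were highest apart from SLC7A11. Only 11 of the 18 were above 0, the lowest at -0.53, and the matched random lists had a median of -0.18. Genes of the unfolded protein response had a median of 0.32 over 17 genes (percentile 99.2), with DNAJB9 at 14.4 against 3.09 FPKM (1.91), SEL1L at 28.2 against 10.7 (1.32) and the chaperone HSPA5 at 248 against 102 (1.28). Here 10 of the 17 were above 0, the lowest at -0.71, and the matched random lists had a median of -0.12. Hypoxia and glycolysis genes had a median of 0.37 over 20 genes (percentile 99.0), with 12 above 0, and 4 higher and 1 lower by 2-fold. BNIP3 was at 138 against 36.7 FPKM (1.88), the glucose transporter SLC2A1 at 27.3 against 7.54 (1.73) and PDK1 at 9.65 against 2.92 (1.44).

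The other lists above random lists were fatty acid genes (median 0.47, percentile 99.7), histone genes (0.69, 99.7), uveal melanoma genes (0.56, 99.2), the xenobiotic response (0.79, 98.6) and housekeeping genes (0.23, 97.9). Among them, ACSL3 was at 148 FPKM in MA against 43.1 in NC (1.76), PLIN2, a lipid droplet coat gene, at 69.0 against 28.8 (1.23) and the desaturase SCD at 731 against 331 (1.14). Of the 15 tested uveal melanoma genes, 11 were above 0, so the list did not move in 1 direction. ID2 was at 24.3 against 5.07 (2.06) and FXR1 at 72.7 against 34.9 (1.04). PRAME, at 248 against 466 (-0.91), and ECM1, at 284 against 457 (-0.69), were lower. AHR, the dioxin receptor, was at 19.2 against 6.63 (1.41), its target TIPARP at 15.8 against 6.63 (1.13) and CYP1A1 at 5.74 against 2.75 (0.85). The linker histone H1-2 was at 36.9 against 12.4 (1.49) and the variant histone H3-3A at 44.0 against 104 (-1.22). H1-4 was at 1.62 against 0.274 (1.04), with only 8 minimum reads in NC. Some other histone genes, such as H2BC4 (1.06 against 0.278), were also under 1 FPKM in NC. Since housekeeping genes stood above random lists, with HPRT1 at 41.3 against 20.4 FPKM (0.98), TFRC at 59.2 against 32.1 (0.86) and SDHA at 31.1 against 44.5 (-0.50), a percentile that high was also reached by genes used as references. The xenobiotic list fell to percentile 95.7 with a pseudocount of 0.1, to 97.2 with random lists matched on length and just below the bound as TPM, and the housekeeping list fell to 96.9 with the match on length. The median of the histone list was 1.18 with a pseudocount of 0.1 and 0.99 as TPM, beyond its spread.

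Melanocyte lineage genes were the lowest list with MA, with a median log2 difference of -1.14 over 15 genes, below all 10000 random lists. None of the 15 was above 0, and 9 were lower by 2-fold or more. The melanosome protein PMEL was at 1251 FPKM in MA and 4027 in NC (-1.69), MLANA at 122 against 375 (-1.62) and the pigment enzyme DCT at 65.2 against 191 (-1.54). The list of reported FTO targets had a median of -0.40 over 10 genes (percentile 2.25), in which ASB2 was at 3.96 against 13.9 FPKM (-1.59) and cyclin D1, CCND1, at 40.3 against 94.1 (-1.20). BNIP3, also of this list, was higher as given above, and 3 of the 10 genes were above 0. The list gives no direction for its members, so its median is no measure of FTO inhibition. The percentile of this list was 2.87 with random lists matched on length.

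**Figure D2:**
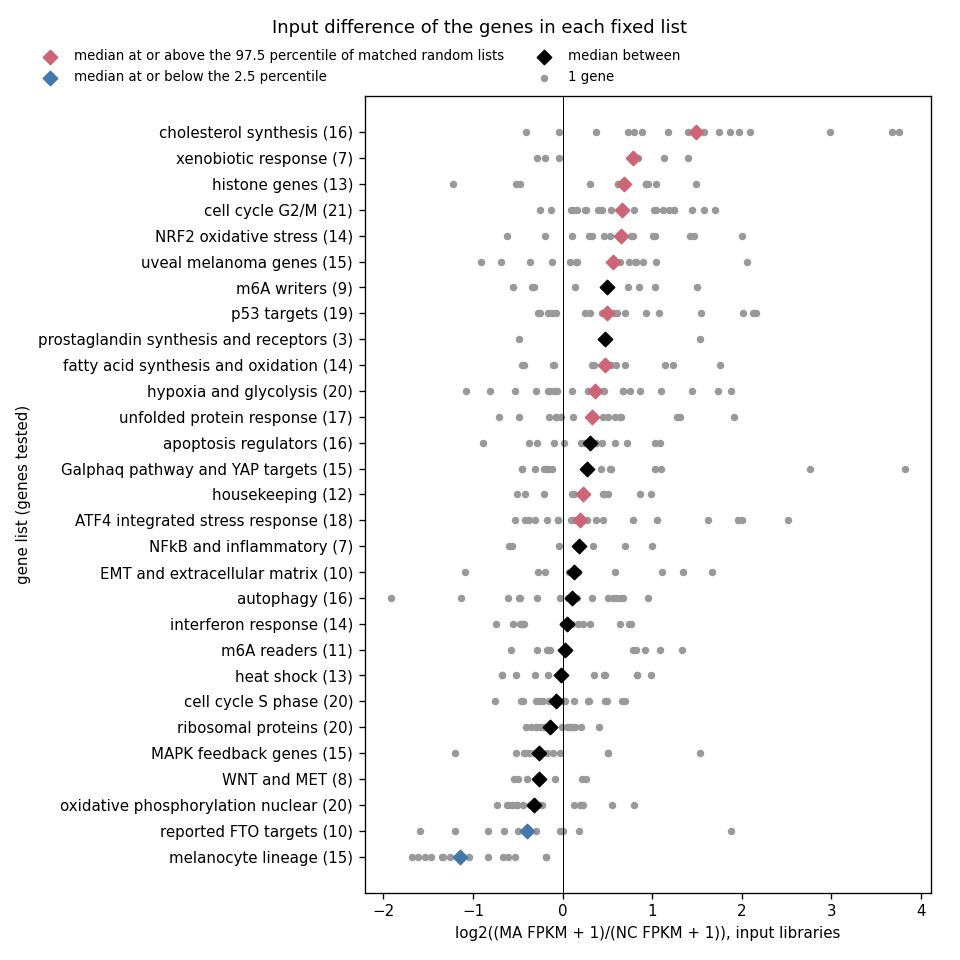
Log2((MA FPKM + 1)/(NC FPKM + 1)) in the inputs (x axis) for each tested gene (grey points) of 29 fixed lists (y axis, number of tested genes in brackets), with each list's median as a diamond, red at or above the upper bound of matched random lists, blue at or below the lower bound (percentile 2.5) and black between. The median of cholesterol synthesis lies highest at 1.49 and that of the melanocyte lineage lowest at -1.14, with all 15 of its genes below 0.

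The remaining lists lay within the range of random lists matched on expression. Genes of the Galphaq pathway and YAP targets had a median of 0.27 (percentile 90.4), although CCN1 and CCN2 (117 against 16.4 FPKM, 2.76) were among the genes most different in the inputs and PLCB4 was at 3.98 against 1.32 (1.10). MAPK feedback genes had a median of -0.26 (percentile 12.3), with EGR1, an immediate early gene, higher in MA (1.54), CCND1 as above and SPRY4 at 15.5 against 22.6 (-0.52). The median of WNT and MET genes was -0.26 (6.74, but 2.01 and so apart with random lists matched on length), with CTNNB1 at 293 against 428 (-0.54), MYC at 45.2 against 64.5 (-0.50) and FZD7 at 10.8 against 14.5 (-0.39). Nuclear genes of oxidative phosphorylation had a median of -0.31 (13.3) and ribosomal protein genes one of -0.14 (75.3), and no gene of either list reached 2-fold. NDUFV1 was at 98.6 against 164 FPKM (-0.73), NDUFB8 at 88.2 against 136 (-0.62) and the log2 difference of CYCS was 0.80, while RPS12 was at 818 against 1090 (-0.41), RPL7 at 731 against 549 (0.41) and RPL8 at 2505 against 3192 (-0.35). Apoptosis regulators (median 0.31, percentile 71.8), autophagy (0.11, 72.9), heat shock (-0.01, 77.9), interferon response (0.05, 43.9), NFkB (0.19, 46.6), EMT and matrix (0.13, 75.1) and prostaglandin genes (0.47, 88.0, 3 genes) also lay between.

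Within those lists some members were apart by 2-fold or more. ATG2A, a lipid transfer gene of autophagy, was at 5.35 FPKM in MA and 23.0 in NC (-1.92) and WIPI1 at 15.2 against 34.6 (-1.13). XIAP was at 7.95 against 3.21 and BIRC2 at 9.37 against 4.06 (1.04), both inhibitors of apoptosis. The EMT regulators SNAI1 (6.66 against 1.41, 1.67) and ZEB2 (27.7 against 10.3, 1.35) and the cadherin CDH2 (16.1 against 6.88, 1.12) were higher, while SNAI2, named after its values were seen, was at 27.0 against 58.6. PLA2G4A, the phospholipase that releases arachidonic acid, was at 14.2 against 4.24 FPKM (1.54). The chemokine CXCL8 was at 1.46 against 0.230 FPKM, with only 7 minimum reads in NC. Chaperones such as HSPH1 (21.5 against 10.3, 0.99), HSP90AA1 (567 against 318, 0.83) and HSPD1 (276 against 154, 0.83) stayed under 2-fold with the pseudocount of 1. IFIH1 (3.81 against 1.82, 0.77), DDX58 (1.64 against 0.570, 0.75) and TAP1 (7.76 against 13.6, -0.74) did so as well, although the FPKM values of HSPH1, IFIH1 and DDX58 themselves differ by more than 2-fold, beyond counting error for DDX58 only. The median of the interferon list was -0.43 (percentile 1.41) when only genes at 5 FPKM or more were kept.

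The m6A machinery was expressed in both inputs. FTO was at 2.95 FPKM in MA and 2.15 in NC, a log2 difference of 0.33, and the other demethylase, ALKBH5, at 22.9 against 23.4 (-0.03, above 0 after rescaling to TPM). Among the writers, VIRMA (26.0 against 8.54, 1.50) and METTL14 (5.50 against 2.17, 1.04, but under 2-fold after rescaling to a median of 0) were higher by 2-fold, followed by WTAP (13.9 against 7.25, 0.85), RBM15 (0.74), CBLL1 (0.50) and ZC3H13 (0.14). The catalytic subunit METTL3 was at 26.7 against 33.6 FPKM (-0.32), METTL16 at -0.34 and RBM15B at -0.55, and the 9 writers had a median of 0.50 (percentile 92.7). Of the readers, YTHDC2 (9.05 against 2.97, 1.34) and YTHDC1 (14.6 against 6.36, 1.08, but under 2-fold after rescaling to a median of 0) were higher by 2-fold. FMR1 (0.93), IGF2BP3 (0.82) and YTHDF3 (0.78) were higher by less, and YTHDF1 (-0.57), PRRC2A (-0.28), YTHDF2 (-0.17), HNRNPA2B1 (-0.16) and IGF2BP2 (-0.15) were lower. HNRNPC was at 0.02 (below 0 after rescaling to a median of 0), IGF2BP1 was under 0.1 FPKM in both inputs, and the 11 tested readers had a median of 0.02 (percentile 64.3).

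Of 31 marker genes of fibroblasts, immune cells, endothelium and epithelium, 17 were in the table and 2 reached 1 FPKM. These were the fibroblast marker LUM, at 4.96 FPKM in NC and higher in MA by 1.13 on the log2 scale, and the lysosomal gene CD68, at 89.9 against 111 (-0.31). None of the endothelial and epithelial markers reached 1 FPKM in either input.

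The NC list held 22067 peaks in 9515 genes and the MA list 19929 peaks in 9075 genes. Their total exonic lengths were closer, 8.77 Mb in NC and 8.62 Mb in MA, because peaks were on average longer in MA (432 bp against 398 bp), while the medians were 300.0 bp in MA and 299 bp in NC. Peaks lay most often in the 3' UTR, 42.1% in NC (exact 95% interval 41.5 to 42.8%) and 42.8% in MA (42.1 to 43.5%). Peaks annotated only as exon made up 33.8% and 34.0%, the 5' UTR 14.4% and 14.9%, and the stop codon 3.54% and 3.46%. Start codon peaks had a share of 6.06% in NC (5.75 to 6.39%) and 4.79% in MA (4.49 to 5.09%). Mitochondrially encoded genes had 11 peaks in each list, in the same number of genes, 9, among them ND1, CYTB and ATP6.

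After merging, 16114 of 21837 NC regions (73.8%, 73.2 to 74.4%) overlapped a MA region, and 15708 of 19734 MA regions (79.6%, 79.0 to 80.2%) overlapped a NC region. Spans included introns, so a peak over more than 1 exon could be shared without a common exonic base. Of the peaks, 59.8% in NC and 55.9% in MA lay within 1 exon. For peaks within 1 exon the shares with a partner were 59.5% in NC and 69.5% in MA. Within each list, peaks without a partner were shorter and less enriched than shared ones. The median fold enrichment was 3.90 for shared and 3.00 for unshared peaks of the NC list, with median lengths of 350.0 and 199 bp. For the MA list the folds were 3.25 and 2.52 and the lengths 351 and 200.0 bp. Unshared peaks lay more often in the 5' UTR, 18.1% against 13.2% of shared peaks in NC and 17.6% against 14.3% in MA. Start codon peaks made up 8.59% of unshared NC peaks (7.88 to 9.35%) and 4.99% of unshared MA peaks (4.34 to 5.71%). With an overlap of at least 50% of both regions, 46.3% of NC and 51.2% of MA regions were shared. With equal peak numbers the order of the lists turned, at 76.4% of NC and 74.7% of MA regions.

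**Figure D3:**
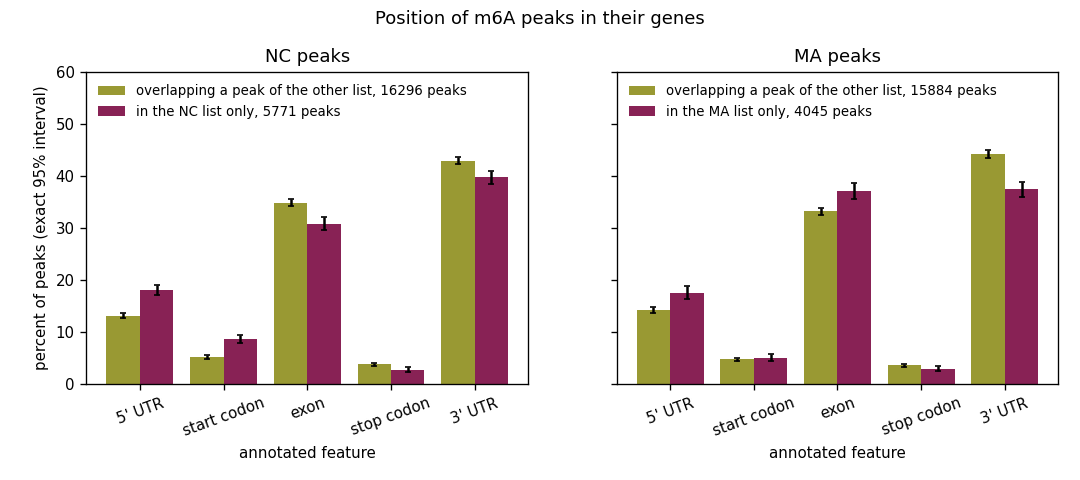
Percent of peaks (y axis, from 0) in each annotated feature (x axis) for NC peaks (left) and MA peaks (right), split into peaks that overlap a peak of the other list (olive) and peaks of that list only (purple), with exact 95% intervals as error bars that cover counting error only. The 3' UTR bar is the tallest in each set, and start codon peaks are 8.59% of the NC-only and 4.99% of the MA-only peaks.

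The shared peaks with the highest fold enrichment in the NC list were in PPP1R26, a phosphatase regulator (chromosome 9, 135484548 to 135485347, exon, fold 27.0), SBF2 (chromosome 11, 9779416 to 9780163, 3' UTR, fold 24.0) and ZBED5 (chromosome 11, 10853694 to 10854782, exon, fold 24.0), on GRCh38.p13. EIF3C, at a fold of 23.8, and CABLES2 followed. Among NC peaks without a MA partner, the highest were in GTF2I (chromosome 7, 74749348 to 74753869, exon, fold 55.0) and at the start codon of MEMO1 (chromosome 2, 31943013 to 31950687, fold 24.0). Those in GOLGA8B, CBS and NPIPA1 had folds of 16.0, 15.2 and 15.0. CBS, the first enzyme of transsulfuration, had 2 peaks in NC and 0 in MA at input levels of 9.06 FPKM in NC and 9.15 in MA, while its copy CBSL had 2 in NC and 1 in MA. Among MA peaks without a NC partner, the highest were in CCZ1B (chromosome 7, 6819904 to 6824641, exon, fold 48.0), THOC3 (chromosome 5, 175964994 to 175967243, exon, fold 47.0) and NOTCH1 (chromosome 9, 136495679 to 136495978, 3' UTR). CT55 and SPCS2 had folds of 15.0 and 14.0, and NOTCH1 had 5 peaks in NC and 4 in MA in all. GTF2I, EIF3C, GOLGA8B, CBS, NPIPA1, CCZ1B and THOC3 have near-identical copies elsewhere in the genome, so the placement of their reads is uncertain.

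By gene, 8489 genes had a peak in both lists, 1026 in NC only and 586 in MA only. Of the m6A writers, erasers and readers, 22 of 23 had peaks in both lists, the exception being IGF2BP1, with none. Among the pigment genes, MLANA had 2 peaks in NC and 0 in MA, and TYRP1, a melanin synthesis enzyme at 1327 FPKM in MA and 1921 in NC, had 0 in NC and 2 in MA. Over all fixed lists, 276 of 533 genes had a peak in both lists, 33 in NC only and 22 in MA only. The 533 include 13 mitochondrially encoded genes whose symbols did not match those of the peak lists. The 9 mitochondrial genes with peaks are therefore not among the 276. In genes at 5 FPKM or more in both inputs the counts were 4969 in both, 473 in NC only and 204 in MA only. With the stricter threshold, which keeps fewer MA than NC peaks, they were 5647, 1833 and 675. With the same number of top peaks in both lists, an alternative chosen after seeing the data, they were 8266, 922 and 809.

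List genes with a peak in NC only included the cell cycle genes CDT1, MCM4 and AURKB, the p53 target ZMAT3, 3 genes of autophagy (ATG7, MAP1LC3B and WIPI1) and 3 ribosomal protein genes (RPL10, RPL11 and RPS27A). Of lipid metabolism, LSS, SREBF2 and CPT1A were in this class, and of stress and metabolism HSPA8, HSPE1, GCLM, NDRG1, PGAM1 and NDUFA1. Others were RELB, CXCL8, DDX58, PTGER4, ETV4, FN1, ITGA5, ECM1, EIF1B, H3-3A, TBP and, as given above, MLANA. Of these, ITGA5 (0.306 FPKM in MA against 0.194 in NC) and PTGER4 (0.770 against 0.356) were under 1 FPKM in both inputs, and CXCL8 and DDX58 in NC. At such low input levels their peak calls are uncertain. SREBF2, the transcription factor of sterol genes, was at 189 FPKM in MA and 250.0 in NC, and HSPA8 at 507 against 729. Those with a peak in MA only included 4 histone genes (H2AC6, H2BC4, H2BC5 and H2BC21), the cell cycle genes CCNE1, PCNA and NUSAP1 and the p53 targets FDXR and SESN1. NUSAP1 had 0 peaks in NC and 3 in MA, at 87.3 FPKM in MA and 39.5 in NC. PDK1, PFKL, UQCRC2, PPARGC1A, BID, EDEM1, HLA-B, TAP1, CXCL3, NFKB2 and TYRP1 were also in this class. H2BC4 (1.06 FPKM in MA against 0.278 in NC), H2BC5, H2BC21, PPARGC1A (0.878 against 0.212), BID and CXCL3 were under 1 FPKM in NC and higher in MA. Their missing NC peaks may be a limit of detection.

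Input levels differed in the direction of the peaks. Genes with a peak in NC only had a median log2 input difference of -0.10 over 770 tested genes, below all 10000 random lists, whose median was 0.10, although 32 of them were higher by 2-fold and 36 lower. Genes with a peak in MA only had a median of 0.39 over 427 genes, above all 10000 random lists (0.16), and 63 of them were higher by 2-fold against 14 lower. Genes with a peak in both lists had a median of 0.16 over 8026 genes, above all 1000 random lists (0.13), with 924 higher and 209 lower by 2-fold. With the stricter peak threshold the median of NC-only genes was 0.07 (percentile 27.2) and that of MA-only genes 0.20 (percentile 83.6).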

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

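No paired analysis was possible because each group had 1 library. Peaks within 1 exon, unmerged peaks, groups by length, random lists matched on length, TPM for lists, equal peak numbers for genes and removal of abundant genes were chosen after seeing the data. Genes 2-fold higher with MA numbered 1801 with a pseudocount of 0.1, 273 with 5 and 1842 as TPM, and 154 were lower with a pseudocount of 5, against 1087 and 315. The ratio of higher to lower genes, 3.45, was 1.77 with a pseudocount of 5, 2.10 after rescaling to a median of 0, 5.67 as TPM, 1.78 among the shortest and 5.78 among the longest of 3 groups by length, and higher genes outnumbered lower ones under each alternative run. Rescaling took 0.10 off every log2 difference before the pseudocount, and TPM added 0.08 and also made the pseudocount smaller relative to the values. Without a filter the counts were equal, since no gene under 1 FPKM can reach 2-fold. Shares of NC and MA regions with a partner were 46.3% and 51.2% at 50% of both regions, 69.9% and 75.4% at 50% of the shorter, and 82.3% and 86.7% for the upper part of each list by enrichment. They were 61.2% and 75.1% with the stricter threshold applied to both lists, 76.4% and 74.7% with equal peak numbers, and 59.5% and 69.5% for peaks within 1 exon. The stricter threshold left 14136 NC and 10951 MA peaks, and genes with a peak were then 5647 in both and 1833 in NC only. At 5 FPKM or more they were 4969 in both, 473 in NC only and 204 in MA only, since fewer genes enter. The median input difference of NC-only genes turned from -0.10 to 0.072, and that of MA-only genes went from 0.39 to 0.20 (percentile 83.6), with the stricter threshold. The cause was not tested except where named. Lists apart from random lists numbered 12 to 15 over the alternatives, against 14. List medians moved within their spread in 112 recomputed values and beyond it in 4, and no called list turned sign. Medians near 0 (m6A readers, S phase, heat shock, interferon and NFkB) did turn. The 20 named input genes all stayed beyond 2-fold in 80 recomputed values, of which 54 moved beyond their spread and 26 within it. Not run were the variants of RIP against input, motifs, mitochondrial genes and exon-only peaks, as listed peaks all had exonic annotations. RIP depth is unknown here, which limits every comparison of peak numbers.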

Other observations

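The groups and genes in the opening paragraphs were chosen after seeing the data. Of 295 pathways named in the authors' gene table with 10 or more tested genes, 6 were in the highest 0.1% of random lists matched on expression and also of those matched on expression and length, and 6 were in the lowest 0.1%. Beside steroid biosynthesis, p53 signaling and the cell cycle, the high ones were homologous recombination, ferroptosis and a herpes simplex virus pathway that consists largely of zinc finger genes. Homologous recombination had a median log2 difference of 0.62 over 39 genes, 12 of them higher by 2-fold with MA, including BARD1 (8.20 FPKM in MA against 1.79 in NC), BRCA1 (15.9 against 5.10) and BLM (9.49 against 3.24). Ferroptosis had a median of 0.43 over 31 genes, with ACSL4, a lipid ligase that favours lipid peroxidation, at 29.3 against 8.16 FPKM and the ferritin light chain FTL at 4374 against 2144. RB1 was at 19.3 against 4.86 FPKM and CCNG2 at 35.4 against 6.24.

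The low pathways were lysosome, N-glycan biosynthesis, ECM-receptor interaction, ABC transporters, bile secretion and ovarian steroidogenesis. Lysosome genes had a median of -0.31 over 109 genes, 8 lower and 1 higher by 2-fold, with the phosphatase ACP5 at 62.0 FPKM in MA against 195 in NC, cathepsin CTSF at 22.6 against 54.0 and CD63, a melanosome and endosome tetraspanin, at 403 against 846. ECM-receptor genes had a median of -0.32 over 32 genes, with HSPG2 at 4.10 against 15.0, AGRN at 18.1 against 44.9 and LAMA1 at 3.79 against 10.3. The glycan enzymes MAN2A2 (13.2 against 29.9) and MGAT5B (3.27 against 8.58) and the transporter ABCB5 (9.43 against 23.9) were lower too. Peaks were also listed in genes with almost no counted reads: 65 genes under 0.1 FPKM in both inputs had a peak in both lists. These included readthrough genes such as ANKHD1-EIF4EBP3 (6 NC and 5 MA peaks) and BCL2L2-PABPN1 (3 and 3), and also FLG (11 and 7) and ZNF197 (7 and 6), so the gene label of such peaks is uncertain.

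The tests below were chosen after their patterns had been seen and had their outcomes described before they were run, but the tests that set length bins to a common median and that used equal peak numbers were added after the first test results, and the interval of the ratio was applied to the length groups after its 1.78 was known, and the labels of the tests on peak numbers and on the calling threshold were changed to undecided after their values were known. Input genes were 2-fold higher more often than lower with MA, 1087 against 315. With the pseudocount of 1, scaling of the libraries as the whole explanation is argued against. The ratio of 3.45 stayed at 2.10 (exact 95% interval 1.86 to 2.37) after rescaling to a median difference of 0. It was 1.77 with a pseudocount of 5, which was not combined with rescaling. The intervals of these ratios count genes as independent, which they are not. Abundant genes are argued against too, since the ratio was 4.51 without the 100 most abundant genes of either library. The difference rose with recovered length, from a median of -0.04 among the shortest of 3 groups by length to 0.28 among the longest. The smallest ratio of the 3, 1.78 (1.43 to 2.22), does not decide against the bound of 1.5 set for it, so a part played by length is left open. After each length bin was set to the median of all genes, the ratio was 3.01 (2.66 to 3.42). This step removed the differences between bins but kept the overall median of 0.11. Length and scaling were not removed together, so the ratio of 3.01 cannot decide whether length explains the imbalance. RNA integrity and fragment selection remain open as sources of the length trend, and an effect of the drug remains a hypothesis, since each condition had 1 library.

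The lists that stood furthest apart were weighed against the same length trend. With random lists matched on recovered length and expression, cholesterol synthesis was at percentile 100, G2 and M genes at 100 and the melanocyte lineage at 0. Recovered length as the explanation is therefore argued against for all 3 lists. Recovered lengths are the smallest that fit and went down to 10 bp. Some fall below the true length, so the match on true length was incomplete. A group of 341 zinc finger (ZNF) genes, chosen after seeing the data, had a median of 0.53, with 62 genes higher and 2 lower by 2-fold, and was also at percentile 100, although these genes were long (median 4141 bp against 3488 bp). The highest were ZNF441 (11.4 FPKM in MA against 0.461 in NC), ZNF627 (23.3 against 3.56) and ZNF823 (5.36 against 0.811). GC content was not tested, and with a single library per condition differences between cultures and an effect of the drug cannot be separated for any of the 4 groups.

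More genes had a peak in NC only than in MA only, 63.6% of 1612 genes with a peak in a single list (61.2 to 66.0%). Lower input levels with MA are argued against as the whole explanation: among 2095 genes with like input levels, 145 were NC only and 67 MA only, and the lower bound of the NC share was 61.7%, with genes counted as independent. The number of peaks called is left open: with the same number of top peaks the share was 53.3% and its lower bound 50.9%, but only the NC list was trimmed for this, which draws the counts together whatever the cause. Weak peaks near the calling threshold are left open as well. For this test only the list being counted was cut to the stricter threshold, and partners were sought in the whole other list. The share of NC peaks with a MA partner went from 73.8% to 80.5%, which is 6.63 percentage points higher. The MA list gained 5.49 points too, as stronger peaks would under any cause. Depth and efficiency of the RIP libraries remain open, as does less or more m6A with the drug, which was not tested.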
